A study of Mus musculus with 5 samples.

How the data were processed

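Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of the transcription factor PU.1, encoded by Spi1, was carried out on AML-246 cells, a mouse acute myeloid leukaemia that lacks p53 and carries a doxycycline-regulated short hairpin RNA against PU.1. Per the labels, leukaemic spleen cells were taken from untreated mice (PU.1 low, 2 libraries) or from mice given doxycycline for 2 days (PU.1 high, 3 libraries), which switches the hairpin off and lets endogenous PU.1 return. The labels call the libraries of each group technical replicates, so those of a group need not come from different mice. The antibody was T-21.

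The only processed file is 1 list of peak summits for the whole series. Per the submitters' processing notes, CASAVA 1.8.2 and MACS2 were used and the genome build was mm10. The MACS2 version and settings, the aligner and the read filters are not given in the sources used here. The file's own name sets high against low, so the list is read here as sites where PU.1 high exceeded PU.1 low, with the untreated libraries as the control. A list called in this direction is meant to leave out sites bound alike in both conditions and sites that were higher before treatment. Since the settings are unknown, it may still hold some of them. The deposited value of each summit is the score on a −log10 scale that the peak caller gave it. Whether it is a p-value or a q-value is not stated. The lowest score, 1.32, lies just above 1.30, the −log10 of 0.05. A score measures how surely a site stands out and depends on depth, so it is not a fold change of binding.

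The list holds no value per library, and how the technical replicates entered the calls is not given in the sources used here. Read depth is therefore unknown, no spread between libraries can be given, and no p-value below refers to a difference between treated and untreated mice. The tests describe how the listed sites are distributed over the genome. Sites and genes are not independent replicates of the cells, and the 95% intervals (Wilson for shares, exact Poisson for counts) cover counting error only.

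Positions are given 1-based on mm10. Genes were taken from a RefSeq gene table of GRCm38.p6, whose chromosome coordinates are those of mm10, with 21631 protein-coding genes on chromosomes 1 to 19 and X. The table gives each gene's start and end but no strand, so the planned distances to transcription start sites were replaced by distances to the nearer of the 2 gene ends. A site within 1 kb of a gene end may thus lie at the start or at the end of transcription. The lower and the upper end below mean the ends with the lower and the higher coordinate. No genome sequence was used here, so the planned search for 16 sequence motifs, the PU.1 core among them, was not run.

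The 11106 sites on chromosomes 1 to 19 and X were compared with 100 sets of random positions, with the same number per chromosome between its outermost gene ends or sites. The two-sided Monte Carlo p is 2 times the share of sets at least as extreme, and 0.0198 is the smallest value that 100 sets can give. Gaps in the assembly were not removed from the random positions, so positions 20 kb to each side of every site served as a second background. For 16 gene lists, the share of genes with at least 1 site within 10 kb of either gene end was compared with that of all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 16 lists and a threshold of 0.05. The lists, the 10 kb window, the random positions and the shifted background were fixed before the data were examined. That plan used transcription start sites in place of gene ends and left assembly gaps out of the random positions. The comparisons of scores near and away from gene ends, of chromosome X with the autosomes, of site clusters and of gene families were chosen after the data were seen. Of the 436 list entries, 1 symbol was not matched, and 406 different genes remained, since some genes stand in several lists. Scores near and away from gene ends were compared by a two-sided permutation test of rank sums with 100000 permutations.

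The genes named in the text follow a rule set beforehand. It takes the 10 highest-scoring sites with the nearest gene end, the 4 list members with the highest-scoring site in each list past the threshold (2 in each other list), the first 2 members in alphabetical order with no site within 50 kb in each list past the threshold, the 5 genes with the most sites within 10 kb (ties broken by the highest score), and Spi1 and Trp53. Genes named outside this rule are said to have been chosen after their values were seen. Of the genes this rule takes, 2 are not reported here. A site is assigned to a gene by distance alone.

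On 20 simulated sets of sites over the 21631 genes, with an extra site given to 50% of the genes of 2 lists, 100% of the changed lists were called. Of 280 tests on the other lists, 5 were called, 1 of them for a list that shares genes with a changed one. Apart from 10% moved to gene ends, these simulated sites were spread uniformly, unlike the real ones. An extra site at 50% of the genes is also a large effect, so these rates need not hold for the real sites. Moving 10% of simulated sites to gene ends gave an expected share near gene ends of 12.9%, and 12.8% was recovered. Since the moved sites were placed within the 1 kb that is counted, this checks the counting only. The alternatives tried were a score of at least 10, merging of summits within 500 bp, other windows, genes of all biotypes, other backgrounds, a random 0.5 of the sites, and, added after the data were seen, gene spans, 1 member per gene cluster (in lists and in families), unshared list members, random positions matched on distance to a gene end and on neighbouring genes for the site clusters, and removal of chromosome X or of large gene families. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.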

Results

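PU.1 is an ETS-family transcription factor that myeloid and B cells need to develop. Its binding was mapped in p53-deficient mouse leukaemia cells in which a hairpin had held PU.1 low and in the same leukaemia 2 days after the hairpin was switched off. The question was where PU.1 gains chromatin binding when it is acutely restored. The data are 1 list of sites for the series of 5 libraries (3 with PU.1 high, 2 with PU.1 low). Each site has the position of its summit and the authors' −log10 score.

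The list held 11111 sites. Of these, 11106 lay on chromosomes 1 to 19 and X. The median score was 8.56, with quartiles of 5.78 and 11.9 and a highest score of 43.3, and 4153 sites (37.4%) scored at least 10. Neighbouring sites lay a median of 54.9 kb apart.

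At Spi1 itself (chromosome 2, 91082374 to 91115759), the gene that encodes PU.1, 1 site was called, with its summit at 91080977, 1.40 kb beyond the lower end of the gene. Its score of 8.31 was close to the median of all sites. The next nearest site lay 219 kb beyond its upper end. At Trp53 (chromosome 11, 69580348 to 69591873), the gene deleted in these cells, the nearest site lay 25.4 kb beyond the lower end with a score of 4.83.

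The 10 highest-scoring sites all lay more than 1 kb from an end of a protein-coding gene. The top site, with a score of 43.3, stood at chromosome 1, 165211023, 1.26 kb beyond the lower end of Tiprl. It was followed by a site 28.0 kb from Fth1 (score 41.7), the ferritin heavy chain gene, and one 5.78 kb from Cracdl (41.5). Sites near 3110040M04Rik (39.7), Peli1 (39.6), Krt80 (39.4), Exoc2 (39.0) and Pcnx (37.6) were also outside genes. Peli1, a ubiquitin ligase gene of Toll-like receptor signalling, lay 44.9 kb from this high-scoring site. Closer to Peli1 were sites of lower score, 8.69 inside the gene and 6.51 at 0.329 kb beyond its lower end. Only 2 of the 10 were inside a protein-coding gene. One of them lay in Cd81, a tetraspanin gene (score 38.5), and the other in Cmip (37.6), 99.4 kb from the nearest gene end.

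Sites were concentrated near genes. Of the 11106 sites, 1269 (11.4%, 95% interval 10.8 to 12.03) lay within 1 kb of an end of a protein-coding gene, against 3.11% ± 0.170 (SD, 100 random sets), a ratio of 3.68. The two-sided Monte Carlo p over the random sets was 0.0198, the smallest that 100 sets can give. The excess was steepest next to the gene end, where 437 sites (3.93%) lay within 100 bp, 11.6 times the random share. Most sites were nevertheless more than 1 kb from any end of a protein-coding gene. A further 5157 sites (46.4%) were inside a gene and more than 1 kb from any gene end, against 38.9% of random positions. Another 4680 (42.1%) were outside genes and also more than 1 kb from any gene end, against 58.0%. The median distance to a gene end was 15.3 kb for sites and 47.9 kb for random positions. Each of these differences lay outside the range of all 100 random sets. The positions 20 kb from each site, which share its surroundings, had 5.24% within 1 kb of a gene end, so that the ratio fell to 2.18 against this background (Fisher's exact test, p = 6.3e-88). This test treated all positions as independent and left out the pairing of sites with their shifted positions, so its p is only a rough guide. With the ends of genes of all biotypes counted, 16.4% of sites lay within 1 kb, against 6.31% of random positions.

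**Figure D1:**
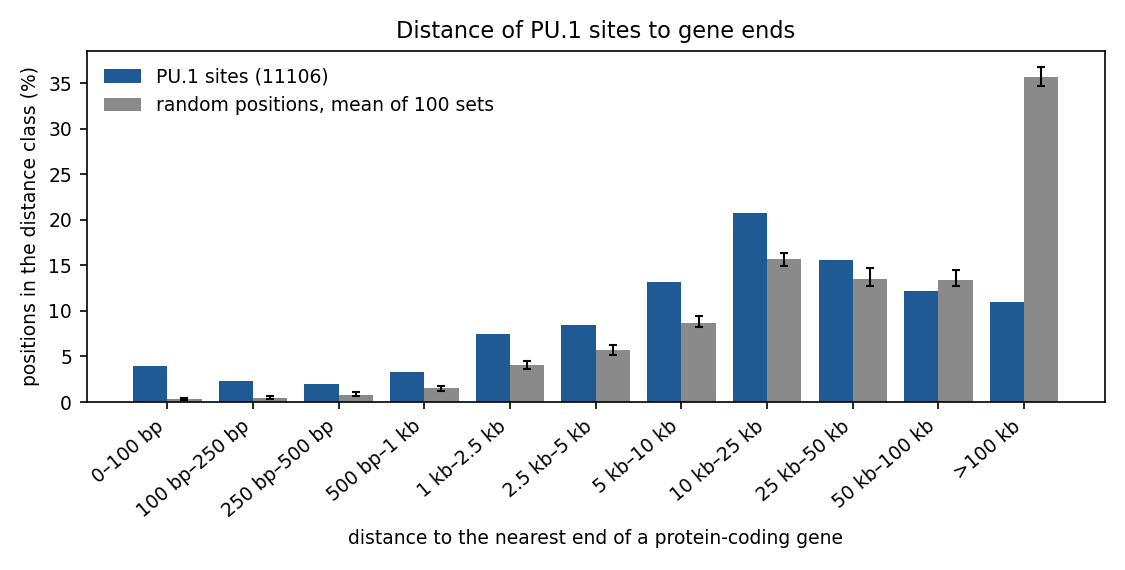
Share of positions (%, vertical axis) in each class of distance to the nearest end of a protein-coding gene (horizontal axis), for the PU.1 sites in blue and for random positions in grey, with bars for the lowest and highest of 100 random sets. Sites exceed random positions in every class up to 50 kb, most of all within 100 bp, and fall below them beyond 50 kb.

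Sites next to gene ends had lower scores than the others. The median score was 7.69 for the 1269 sites within 1 kb of a gene end and 8.64 for the other 9837, a difference of −0.95 (95% bootstrap interval −1.14 to −0.46, permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give). From the lowest to the highest quartile class of scores, the share of sites within 1 kb of a gene end was 14.2%, 11.6%, 10.6% and 9.09%.

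Genes of the monocyte and macrophage, neutrophil, known PU.1 target, antigen presentation and innate immune lists carried sites more often than other genes. A site lay within 10 kb of an end of 4838 of the 21631 protein-coding genes (22.4%). Of the 16 gene lists, 7 exceeded the remaining genes, 0 fell below them and 9 did not pass the threshold. The highest shares were in the monocyte and macrophage list (22 of 30 genes, 73.3%), the neutrophil list (23 of 32, 71.9%), the list of known PU.1 targets (20 of 29, 69.0%) and the MHC class II and co-stimulation list (13 of 19, 68.4%). The lists of pattern recognition, Fc and lectin receptors (20 of 34, 58.8%), inflammatory cytokines and NF-kB feedback (16 of 28, 57.1%) and lysosome and phagocytosis genes (17 of 30, 56.7%) followed. The adjusted p of these 7 lists (Fisher's exact test, two-sided) ranged from 3.3e-08 for the first 2 to 0.00016 for the cytokine list. The lists overlap, with 17 of the 29 known targets standing in another list too. Within 50 kb of an end, 10717 of the 21631 protein-coding genes (49.5%) had a site, so the lack of one at that distance is common.

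**Figure D2:**
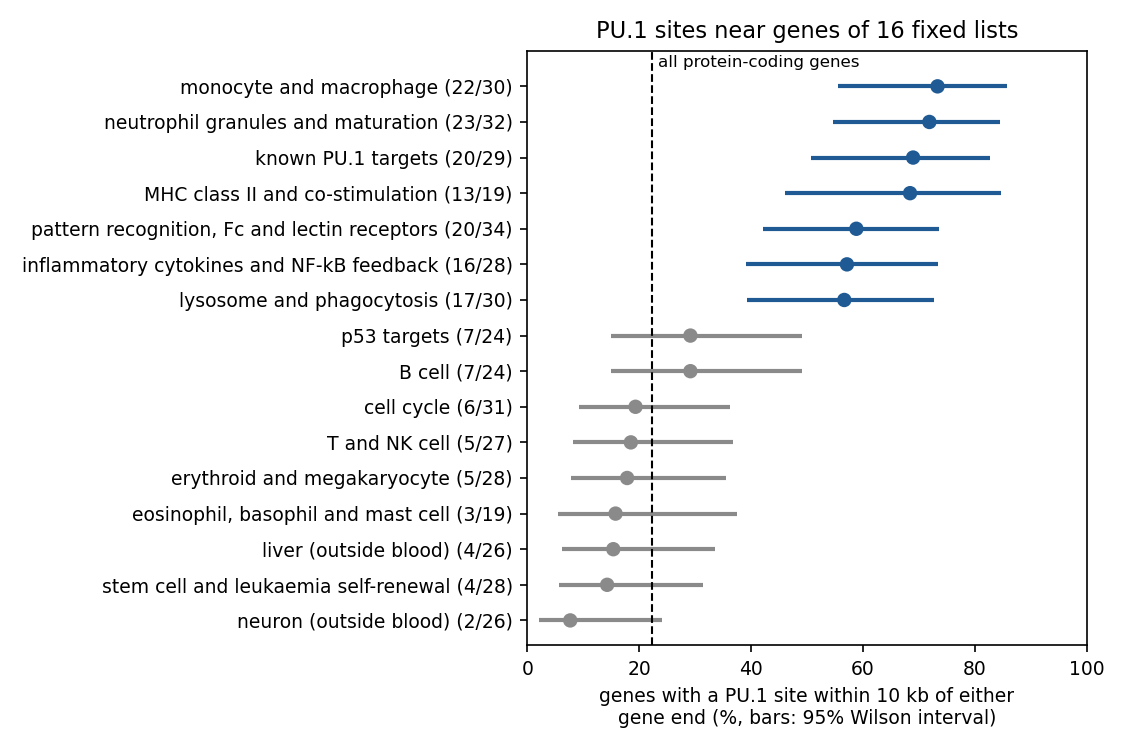
Share of the genes of each list with a PU.1 site within 10 kb of either gene end (%, horizontal axis), with 95% Wilson intervals and the number of genes in brackets. The 7 lists past the threshold, in blue, lie between 56.7% and 73.3%, and the other 9, in grey, between 7.69% and 29.2%; the dashed line marks 22.4%, the share of all protein-coding genes.

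In the neutrophil list, Ncf4 (chromosome 15, 78244164 to 78262582), a subunit gene of the phagocyte NADPH oxidase, had 4 sites, all inside the gene, with scores from 2.32 to 19.99. Csf3r (chromosome 4, 126023441 to 126044975), the receptor for the granulocyte growth factor G-CSF, had 2 sites, of which the one inside the gene scored 18.5. Ltf, the gene of the granule protein lactoferrin, had 4 sites with a highest score of 18.0. Ctsg and Lcn2, which encode the granule proteins cathepsin G and lipocalin, had 0 sites within 50 kb. Ncf4 and Csf3r also stand in the list of known PU.1 targets, as does Fcgr1, the high-affinity IgG receptor gene, with 1 site of score 15.6. Among the known targets, Egr1 and Irf8, both genes of transcription factors of monocyte development, had 0 sites within 50 kb.

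In the monocyte and macrophage list, Marco (chromosome 1, 120474538 to 120505024), a scavenger receptor gene, had a site of score 29.8 that lay 7.01 kb beyond its lower end. Msr1, another scavenger receptor gene, had a site of score 19.4 located 2.02 kb beyond its upper end. Tlr2, a receptor for bacterial lipoproteins, had a site of score 18.8 inside the gene, and Adgre1, a macrophage surface receptor gene, one of 17.5 at 0.811 kb beyond its lower end. Clec4e and Irf8 had 0 sites within 50 kb.

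**Figure D3:**
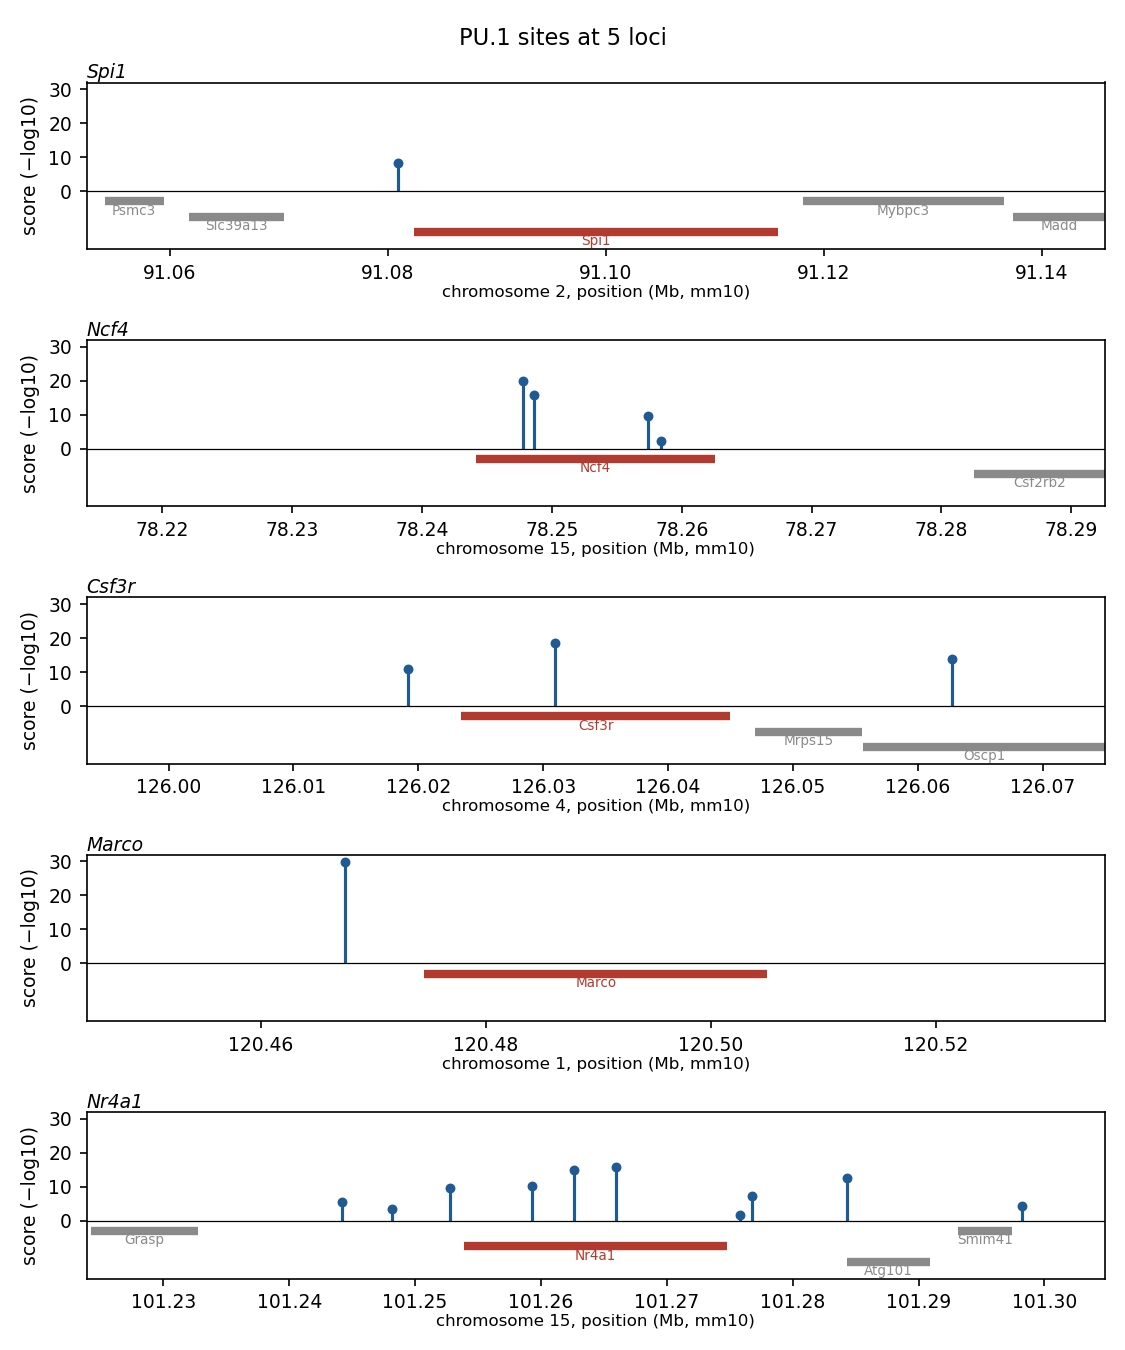
PU.1 sites at 5 loci, each shown with 30 kb on either side of the gene. Blue stems mark summits, with the authors' −log10 score on the vertical axis and the mm10 position (Mb) on the horizontal axis; the gene named above each panel is in red and neighbouring protein-coding genes in grey. Spi1 has a single site of score 8.31 outside the gene, whereas 9 sites lie within 10 kb of the ends of Nr4a1.

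In the antigen presentation list, Ciita, the master regulator of MHC class II genes, had 3 sites with a highest score of 14.2 located 9.27 kb beyond its lower end. The protease genes Lgmn (score 15.5) and Ctss (14.7) and the checkpoint ligand gene Pdcd1lg2 (13.4) carried sites as well. All 19 genes of this list had a site within 50 kb. Among receptors, Fcer1g, the signalling chain shared by several Fc receptors, had a site of score 26.0 that lay 0.374 kb beyond its upper end. The lectin receptor gene Clec4a2 had a site of score 21.8 inside the gene, and the inhibitory receptor gene Pilra had 4 sites with scores from 7.48 to 19.1. Card9, an adaptor of lectin receptor signalling, had 0 sites within 50 kb.

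In the cytokine list, Il12b had 2 sites with a highest score of 17.9 at 0.413 kb beyond its upper end. Il1a had 4 sites (highest score 15.5), and Il1rn, the gene of the interleukin-1 receptor antagonist, 2 sites (highest score 14.01). Tnfaip3, a feedback inhibitor of NF-kB, had 1 site inside the gene with a score of 14.2. The neutrophil chemokine genes Cxcl1 and Cxcl2 had 0 sites within 50 kb. In the lysosome list, the cathepsin genes Ctsd (score 24.0) and Ctsh (21.4) and the prosaposin gene Psap (16.3) led, while Atp6v1h and Ctsb had 0 sites within 50 kb.

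The other lists were not distinguishable from the remaining genes, with adjusted p between 0.19 and 0.83 (Fisher's exact test). Some of these calls depended on the setting. With each site given to its nearest gene end only, the stem cell and leukaemia list (odds ratio 2.70, exact test, adjusted p = 0.019) and the p53 target list (2.70, 0.034) exceeded the other genes and the neuronal list fell below them (0.275, 0.041), and at a score of at least 10 the B cell list exceeded them (3.52, 0.036). Of the stem cell and leukaemia self-renewal genes, 4 of 28 (14.3%, 95% interval 5.70 to 31.5) had a site. They included Myc, with a site of score 13.99 that lay 9.42 kb beyond its upper end, and Flt3, with one of 12.7 inside the gene and 0.093 kb from its upper end. B cell genes had a site in 7 of 24 cases (29.2%), among them Rag2, a gene of antigen receptor recombination, with a site of score 20.6. T and NK cell genes had a site in 5 of 27 cases (18.5%), with Cd5 (21.2) and Cd4 (14.2) highest. Erythroid and megakaryocyte genes had one in 5 of 28 cases (17.9%), with Vwf (20.4) and Ermap (13.4) highest, and eosinophil, basophil and mast cell genes in 3 of 19 cases (15.8%), with Hdc (13.9) and Ear2 (12.3) highest.

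Cell cycle genes had a site in 6 of 31 cases (19.4%), with Rb1 (18.1) and Ccnd3, which had 4 sites (highest 17.9), in front. Targets of p53 had one in 7 of 24 cases (29.2%), with Sesn2 (12.5) and Btg2 (8.22) highest. Of the lists from outside blood, 4 of 26 liver genes (15.4%) and 2 of 26 neuronal genes (7.69%) had a site. The highest-scoring liver gene, Apoa2 (26.0), shared its summit with Fcer1g, which lay 0.374 kb from it against 8.34 kb for Apoa2. Cyp8b1 (12.99) was the next liver gene, and Grin1 (15.8) and Rbfox3 (8.36) were the 2 neuronal genes.

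The 7 lists also exceeded 10000 random gene lists matched on the number of transcripts and of neighbouring genes, with adjusted p of at most 0.00091 (two-sided Monte Carlo test). With a window of 1 kb instead of 10 kb, 4 of them passed. The monocyte and macrophage and the lysosome lists fell to an odds ratio of 1.86 each (exact test, adjusted p = 0.60), whereas the antigen presentation list missed the threshold at an odds ratio of 4.25 (adjusted p = 0.096), within the range of 4.05 to 5.47 of those that passed. With a random 0.5 of the sites, the pattern recognition list did not pass (odds ratio 2.22 instead of 4.92, exact test, adjusted p = 0.12).

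Some genes drew many sites. Nr4a1 (chromosome 15, 101253902 to 101274795), a nuclear receptor gene of monocytes, had 9 sites within 10 kb of its ends, with scores from 1.77 to 15.9. Kcnk13, a potassium channel gene, had 7, none scoring above 8.64. Cradd (highest score 25.7), Pik3r5 (17.2), a phosphoinositide kinase subunit gene, and P2ry12 (17.2), a purinergic receptor gene, had 6 each. Across the genome, 44 clusters that held at least 5 sites within 25 kb were counted. Not all of them lay at genes, and the largest, with 7 sites each on chromosomes 10 and 12, had no protein-coding gene within 10 kb. Since sites lie near genes more often than uniform random positions, which held 0.07 clusters per set on average, the count was also set against 100 sets of random positions matched on chromosome, distance to a gene end and number of genes within 100 kb. These held 0.35 clusters on average and 2 at most, for a two-sided Monte Carlo p of 0.0198, the smallest that 100 sets can give.

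Chromosome X carried few sites. It had 186 sites for 966 protein-coding genes, or 19.3 per 100 genes (95% Poisson interval 16.6 to 22.2), against 52.8 on the autosomes together and 31.7 to 71.3 on single autosomes. The ratio of X to the autosomes was 0.364 per gene and 0.242 per Mb. The median score on X was 7.78, against 8.56 on the autosomes, a ratio of 0.909 whose 95% bootstrap interval, 0.826 to 1.05, includes no difference. Cybb, the X-linked NADPH oxidase subunit gene, named here after its values were seen, had 0 sites within 10 kb and 4 within 50 kb of its ends.

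**Figure D4:**
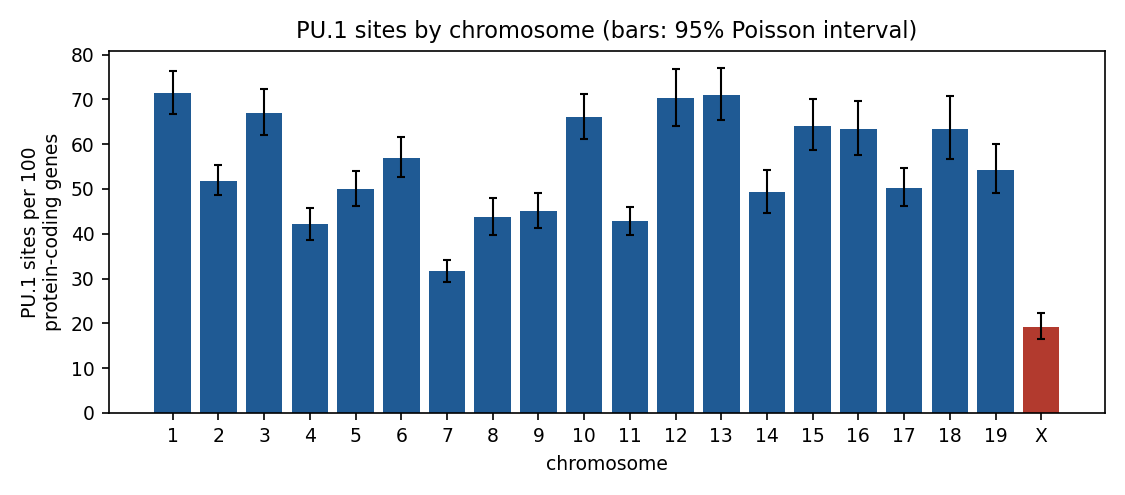
PU.1 sites per 100 protein-coding genes (vertical axis) on each chromosome (horizontal axis), with 95% Poisson intervals for the number of sites. Chromosome X, in red, has 19.3, below the lowest autosome at 31.7.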

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

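The list includes 4 summits on the mitochondrial genome, at positions 5991, 6255, 11206 and 12957, with scores of 3.14, 1.68, 2.26 and 3.39. They lie outside the chromosomes used in the comparisons and are given as signal in data that no comparison used. Their number is above 3, the limit that a count of 0 allows, which is not an expected number for this genome. All 4 scores are below the lower quartile of 5.78, and no control measurement of mitochondrial reads was used here.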

How the results depend on the processing

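The scores near gene ends, the ratio for chromosome X and the alternatives with gene spans, 1 member per gene group, unshared members, removal of chromosome X and removal of large families were chosen after the data were seen. Raising the minimum score to 10 left 4153 of the 11111 sites. With a 1 kb window, 4 instead of 7 lists exceeded the other genes, since the odds ratios of the monocyte and macrophage and the lysosome lists fell to 1.86 and that of the antigen presentation list, at 4.25, missed the threshold. Per Mb, the ratio of X to autosomes was 0.242 instead of 0.364. When each site was given to its nearest gene end only, whatever the distance, 9 lists passed. Under that rule the stem cell and leukaemia list turned from a lower to a higher share (odds ratio 2.70, Fisher's exact test, adjusted p = 0.019, range over all alternatives 0.019 to 1), and the cause was not tested. The p53 target list passed under that rule too (adjusted p = 0.034 by the exact test, range 0.034 to 1), and the neuronal list fell below the other genes (adjusted p = 0.041 by the exact test, range 0.013 to 0.93). The neuronal list also fell below with gene spans and 10 kb on each side, against random lists matched on length as well. At a score of at least 10, the B cell list passed (odds ratio 3.52, exact test, adjusted p = 0.036, range 0.036 to 1). With a random 0.5 of the sites, the pattern recognition list did not (odds ratio 2.22, exact test, adjusted p = 0.12, range 6.4e-07 to 0.12). Of 176 list results under the 11 alternatives, 167 stayed on their side of the threshold, 4 newly passed in their former direction, 4 no longer passed and 1 turned. The same 7 lists passed under every alternative other than the 1 kb window and the random 0.5 of the sites. The share of sites near gene ends exceeded its background under all 6 alternatives tried, and scores near gene ends were lower under all 5 tried for them, by 0.46 to 1.05. No paired analysis was possible because the file holds no values per replicate, and for the same reason no replicate was left out. The motif alternatives were not run, and unknown read depth limits what can be said of sites outside the list.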

Other observations

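The tests of chromosome X, of scores near gene ends, of the granule classes, of gene families with all members and with 1 per group, of 1 list member per gene group and of the background without large families were chosen after the data were seen, and those of one copy of X and of the granule classes after the result they measure; the matched random lists were set before.

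Beyond the fixed lists, 364 gene families, formed from the letters that begin a gene symbol and with at least 8 members, were searched for an excess or a lack of sites within 10 kb (Fisher's exact test, two-sided, adjusted over the 364). A family here is a symbol stem, so it can hold genes of unrelated function as well as members of the fixed lists. In 4 families more genes carried a site than among the other genes, namely the stems Cd (43 of 100 by the exact test, adjusted p = 0.00037), Clec (19 of 33, 0.00077), Il (35 of 83, 0.0028) and Rassf (7 of 10, 0.045). Neighbouring members can share a site, as do Clec12b and Clec1a, an example chosen after their values were seen. With 1 member kept per group of family genes within 100 kb, 1 of the 4 stems passed, Cd (34 of 74 by the exact test, adjusted p = 0.0014). Il (24 of 58, 0.12), Clec (6 of 15, 0.66) and Rassf (7 of 10, 0.13) did not. The odds ratio fell from 4.68 to 2.38 for Clec, but was 2.55 before and 2.47 after for Il, of which fewer genes were tested, and 7.45 in both for Rassf, which lost no gene. Of the 43 Cd genes with a site, 31 were among the 73 Cd genes that stand in no fixed list. Examples chosen after their values were seen are Cd83 (4 sites, highest score 28.1) and Cd180 (4 sites, 23.1). Fewer genes carried a site in 10 families, among them Olfr (21 of 1110, 1.89%), the olfactory receptors, and Vmn (2 of 355), the vomeronasal receptors. These 2 were the ones of the 10 that still passed with 1 member kept per group. At some of the other stems so few genes remained (1 for Defa, 3 for Rhox, 4 for Krt) that no lack could have passed. Their loss of the call therefore does not show that the lack came from shared sites. Members removed in this step were counted among the other genes.

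Without the Olfr, Vmn, Krtap, LOC and Gm genes, 24.96% of the remaining 18881 genes had a site, and all 7 lists still passed.

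The excess of sites in the immune gene lists may reflect where PU.1 binds in these cells, and 2 technical explanations were tested. Gene density or transcript number is argued against, since 7 of the 7 lists exceeded matched random lists. Neighbouring genes sharing one site is argued against for the 5 of these lists that have members within 100 kb of each other, since all 5 passed with 1 member kept per group (odds ratios 3.48 to 8.81). The other 2, the known targets and the lysosome list, have no such members, so that this test did not bear on them. Chromatin that is open in these cells would draw sites to the same genes, and no measure of accessibility was used here, so this remains untested.

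Lower scores near gene ends may have several sources. That gene-dense regions score lower is argued against, since within 5 classes of neighbouring gene number the difference was −0.88 (95% bootstrap interval −1.12 to −0.42), close to the overall −0.95 and negative in each class. Higher background of the untreated libraries at gene ends, or PU.1 already bound there when it was low, cannot be told apart from weaker gains, because the list holds no reads per library.

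Sparser or less annotated genes on X are argued against as the source of the low number of sites there. Of 966 X genes, 81 (8.39%) had a site within 10 kb, against 196.7 expected from autosomal genes matched on neighbouring genes and transcripts, with 148 as the lowest of 10000 draws (two-sided Monte Carlo p of 0.0002, the smallest that these draws can give). One copy of X in these cells may contribute. The ratio of median scores of 0.909 cannot decide this, since scores need not follow reads in proportion and sites under the threshold are missing. Repeats and mappability on X were not tested.

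Within the neutrophil list, sites lay at genes of secondary and tertiary granules (5 of 7, namely Ltf, Camp, Ngp, Mmp8 and Mmp9) and at 0 of 4 primary granule genes (Mpo, Elane, Prtn3 and Ctsg), classes chosen after the values of their genes were seen. A difference between the granule classes, which are made at successive stages of neutrophil development, is a hypothesis that these 11 genes cannot settle. Fisher's exact test gave a two-sided p of 0.061. Since 5 of the 11 genes carried a site, 0 of 4 is already the most extreme split in this direction. No lack at the primary granule genes could therefore have passed, and 0.061 is not a near miss. The neighbouring genes Elane and Prtn3 were also counted as separate genes. Within 50 kb, 5 of 7 and 2 of 4 genes had a site.

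The 11111 summits share only 1333 different scores, and 198 of them have a score of exactly 6.57127.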
